A study of Mus musculus with 12 samples.

How the data were processed

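Right atrial RNA of adult mice was profiled by RNA sequencing, with 6 libraries labelled control and 6 labelled iNICD. Per the labels' protocols, the iNICD mice and their littermate controls were 2 to 3 months old when they were given doxycycline chow for 3 weeks, the atria were taken without a washout period, total RNA was extracted with Trizol and libraries were made by Illumina protocols. Whether each library came from a single animal is not spelled out beyond 6 different atrial samples per group, so the p-values describe the spread between these samples. Sex was not given in the labels.

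The values used were the CPM (counts scaled to the library total) that the authors deposited, 1 column per library, for 41264 rows that hold 40690 Ensembl gene identifiers. The 574 rows that repeat an identifier carried the same values and were used once. STAR 2.4.0b and featureCounts are named in the submitters' processing notes. Genome build, annotation release, strand setting and the treatment of reads with several alignments are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies could share reads in these values. The table also carries the GC content of each gene in percent, deposited by the authors with the gene annotation, which was used for matching genes in 1 check. No other per-sample column was present beyond the 12 mapped ones.

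In each library every CPM value above 0 was a whole multiple of the smallest one, within a tolerance of 0.001 reads for 100% of the values, so whole reads could be recovered. The depth was 12015650 to 22716190 reads assigned to genes, at least 99.9% of them in the table's rows, and 21323 to 22750 genes were above 0. At these depths 1 read corresponds to less than 0.1 CPM, so a gene at the filter limit of 1 CPM rests on at least 12 reads. Libraries of a group differed by far more than counting noise, with a chi-square per degree of freedom of 9.22 to 88.9, so none was a repeat of another. Pearson's r of log2 values between libraries of a group was 0.958 to 0.991.

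CPM are not counts, so the main test was limma with a trend and robust empirical Bayes on log2(CPM + 0.5), without a replicate block. Genes at 1 CPM or more in at least 6 of the 12 libraries were kept (14336 kept, 26354 not), and p-values were adjusted by Benjamini-Hochberg over the kept genes with a threshold of 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes. They compare iNICD with control, and errors are standard errors of the fit. Mean levels are given with SD over the 6 libraries of a group. Single genes were also compared by an exact two-sided permutation test of mean log2 values, which has 924 relabellings and a smallest possible p of 0.0022.

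The 41 gene lists, the 23 key genes and the rule for naming others were fixed before the data were examined. Lists with at least 5 kept genes (37 of 41) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each was also tested with an estimated correlation and with fry. The genes named are the key genes, the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between groups, and up to 4 called members of each list with the smallest adjusted p, which makes 102 genes. Predicted genes were passed over. Some of the named genes are not reported here. Genes named outside this rule were chosen after their values were seen.

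The alternatives were pseudocounts of 0.1 and 2, no filter, a filter on a mean of 5 CPM, median-of-ratios and quantile scaling, limma without robust estimation, array weights, a replicate block, a covariate of log2 Xist, stricter thresholds and each library left out in turn. The quasi-likelihood test of edgeR (TMM) and DESeq2 were run on the recovered reads as alternatives. Alternatives added after seeing the data were a covariate for the RNAs Gm42418 and Rn7sk, leaving out the 3 libraries rich in them, fits on the libraries with high or with low Xist alone, and leaving out control 4 together with the Xist covariate.

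Gene positions came from GENCODE M21 (GRCm38), matched by Ensembl identifier, with 14309 of the 14336 kept genes found. Adjacent genes were neighbours by start among the kept genes, and calls were shuffled 10000 times within 10 bins of expression. The tests were tried on simulated reads with the real means and depths and the overall trend of spread with level. In them 200 genes with a mean of at least 2 CPM were changed, in equal numbers up and down. Genes were drawn independently. The spread of single genes, correlation between genes and libraries that stand apart were not simulated, so the rates below may not carry over to the data. With 14343 genes tested, limma recovered 100% of the genes changed 2-fold or more and 52% of those changed 1.5-fold, and 4.35% of its calls were false. The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.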

Results

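Right atrial RNA was sequenced in 12 libraries, 6 of littermate controls and 6 of iNICD mice, after doxycycline chow for 3 weeks. The series title describes transient Notch activation and sick sinus syndrome in mice, and iNICD is the genotype label of the group in which the Notch pathway was activated. Notch1 is a receptor whose intracellular domain, once released, acts in the nucleus with the DNA-binding protein RBPJ. Each library held 12015650 to 22716190 reads assigned to genes, and 14336 genes were high enough to test.

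The comparison asked how the right atrial transcriptome of iNICD mice differed from that of littermate controls. Notch1 (ENSMUSG00000026923, chromosome 2, 26457903 to 26516663, GRCm38) was at 246 ± 33.8 CPM in controls and 4335 ± 906 CPM in iNICD (SD, n = 6 each). The levels were 242, 268, 293, 245, 237 and 192 CPM in controls 1 to 6, and 4412, 5358, 3605, 5286, 3064 and 4287 CPM in iNICD 1 to 6. The 6 libraries of each group therefore carried the Notch1 level of their label. The log2 fold change was 4.12 (SE 0.14, limma, Benjamini-Hochberg adjusted p = 3.8e-11, exact permutation p = 0.0022). Reads of a transgene and of the endogenous gene are not told apart in these values, so the level covers both.

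Canonical Notch target genes rose with Notch1. Nrarp, a feedback inhibitor of the pathway, went from 12.05 ± 1.57 to 175 ± 48.1 CPM (log2 fold change 3.77), Hes1 from 21.6 ± 4.44 to 85.4 ± 7.28 CPM (1.98), Heyl from 24.0 ± 3.07 to 80.8 ± 9.99 CPM (1.73) and Hey1 from 26.3 ± 2.85 to 76.6 ± 12.7 CPM (1.51), all SD with n = 6 and without overlap between the groups. The transcriptional repressors Hes1, Heyl and Hey1 belong to the direct target family of the pathway, but its member Hey2 was at 4.09 ± 0.866 CPM in controls and 3.99 ± 0.737 CPM in iNICD (SD, n = 6), a log2 fold change of -0.03. Of the 10 kept genes of the Notch target list, 4 rose and none fell, while adjusted over the list alone 4 rose and 1, Gata2, fell. The list was higher by camera (adjusted p = 0.00015) with a median log2 fold change of 0.16 and a mean of 0.88, and adjusted p = 0.068 with an estimated correlation. Among receptors, ligands and processing genes, Jag1 (0.64), Aph1b (0.48) and Notch1 rose and the ligand Jag2 fell by 1.16 on the log2 scale, with 4 of 24 genes changed (adjusted over the list alone 5 of 24) and camera adjusted p = 0.61. The Aph1b call was lost when control 3, iNICD 1, iNICD 2 or iNICD 3 was left out.

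**Figure D1:**
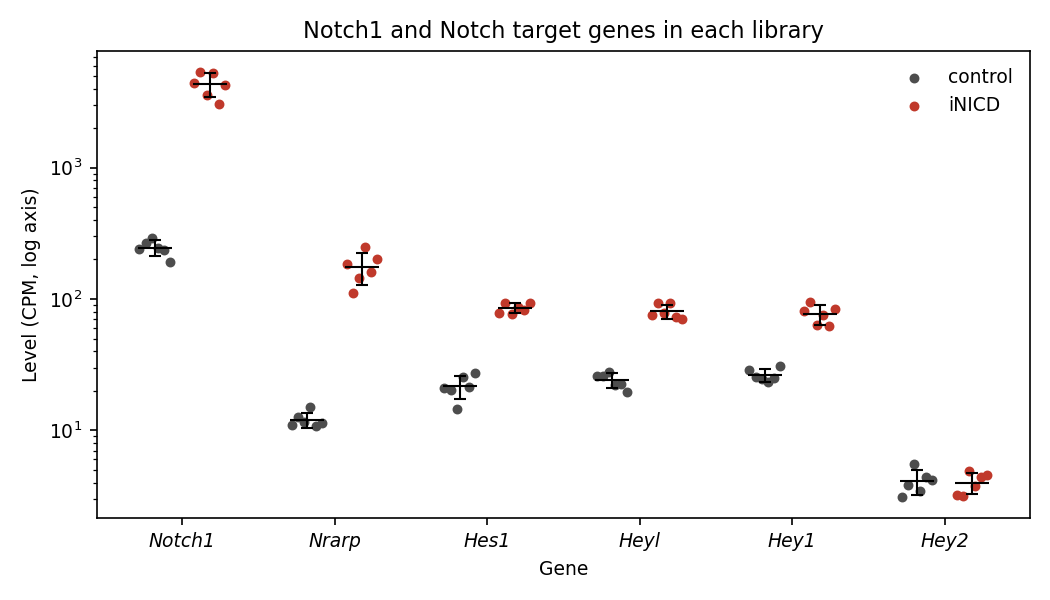
Level of Notch1, Nrarp, Hes1, Heyl, Hey1 and Hey2 in CPM on a log axis, with 1 point per library (6 control in grey, 6 iNICD in red) and black bars for the mean and SD. Notch1 lies at 192 to 293 CPM in controls and 3064 to 5358 CPM in iNICD, and of the 6 genes drawn the groups overlap for Hey2 alone.

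Across the transcriptome, 698 genes were higher and 264 lower in iNICD (limma, Benjamini-Hochberg adjusted p under 0.05), which is 6.71% of the genes tested. Of the 14336 genes tested, 658 had no overlap between the 6 control and 6 iNICD libraries, where chance gives 0.216% of genes, and 576 of the 962 called genes were among them. A log2 fold change of at least 1 was reached by 178 higher and 46 lower genes. The split of 72.6% higher moved with the scaling between libraries, to 61.6% with median-of-ratios scaling (616 higher, 384 lower) and 59.7% with quantile normalization (602 higher, 407 lower).

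The largest changes were ranked among called genes without overlap between the groups and with a mean of at least 5 CPM in the higher group. Under this rule the largest rises beside Notch1 and Nrarp were led by genes close to absent from control atria. Lrrc8e, a subunit of volume-regulated anion channels, went from 0.693 ± 0.345 to 54.0 ± 16.3 CPM (log2 fold change 5.51, SE 0.22) and Cck, which encodes the peptide cholecystokinin, from 0.648 ± 0.417 to 39.9 ± 11.6 CPM (5.17, SE 0.26), SD with n = 6 each. They were followed by AW011738 (3.76), the M-band protein gene Myom3 (3.41), the mitochondrial folate enzyme gene Mthfd2 (3.36), the mast cell protease gene Mcpt4 (3.00), Igfbpl1 (2.86) and the lipoprotein receptor gene Lrp1b (2.78). The largest falls under the same rule were in Noct (-1.97), Lgi3 (-1.90), Nacad (-1.81), Nppa (-1.53), the ciliary neurotrophic factor receptor gene Cntfr (-1.49), the ketone body enzyme gene Bdh1 (-1.48), Ntsr2 (-1.31), Tmem117 (-1.31), Aif1l (-1.28) and Cnksr1 (-1.23). The largest adjusted p among these 20 genes was 0.028, for Cnksr1, whose call was lost without control 2, iNICD 2, iNICD 3 or iNICD 6. Cnksr1 was at 17.6 CPM in control 4 and at 3.76 to 5.55 CPM in the other controls. Without control 4 its log2 fold change was -0.92.

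Genes that mark the atrial myocardium fell together. Nppa, the atrial natriuretic peptide, dropped from 6733 ± 985 to 2374 ± 558 CPM (SD, n = 6), the atrial light chain Myl7 from 5064 ± 163 to 2284 ± 401 CPM and the light chain Myl4 from 7253 ± 632 to 4022 ± 434 CPM. The log2 fold changes were -1.53 for Nppa, -1.17 for Myl7 and -0.85 for Myl4, and sarcolipin (Sln), an inhibitor of the calcium pump, was at -0.71 with adjusted p = 0.00018. In the atrial identity list 8 of 15 genes fell and none rose, and adjusted over the list alone 10 fell and 1, Pam, rose. The list was lower by camera (adjusted p = 2.7e-11, median log2 fold change -0.47), and it was the one list past the threshold with an estimated correlation, at adjusted p = 0.015. In the sarcomere list Mybpc3 (0.61) and Myom1 (0.24) rose, and Ldb3 (-0.40) and Cryab (-0.44) fell, among 21 genes with a median of -0.15 (adjusted over the list alone 4 rose and 6 fell), and camera gave adjusted p = 0.052. The sarcomere list was past the threshold and lower without control 1 (camera adjusted p = 0.028), control 2 (0.031), control 3 (0.018), control 5 (0.047), iNICD 3 (0.049), iNICD 4 (0.021), iNICD 5 (0.022) or iNICD 6 (0.035), with a pseudocount of 0.1 (0.048), the filter on a mean of 5 CPM (0.041), the replicate block (0.048) and the Xist covariate (0.013), but not under median-of-ratios scaling (0.13) or quantile normalization (0.57, median -0.08). The Myom1 call was lost under median-of-ratios and quantile scaling and with the replicate block, and the Myom1 and Cryab calls held in 3 and 6 of the 12 fits that each left out 1 library. In the ventricular identity list 1 of 6 genes rose, Lbh (1.03), likewise adjusted over the list alone, with camera adjusted p = 0.74.

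**Figure D2:**
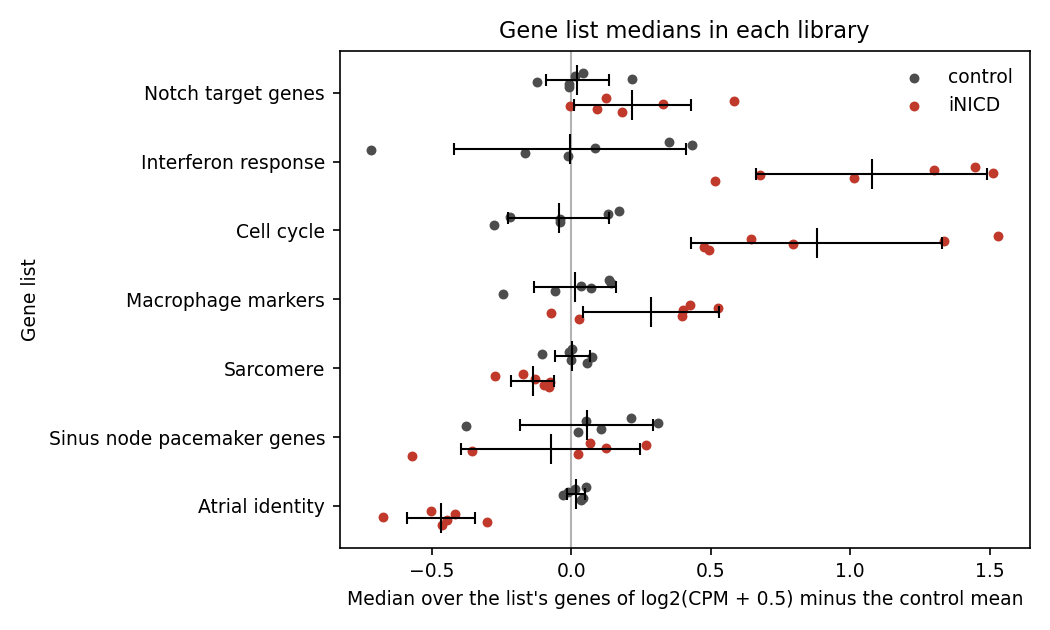
Median over the genes of 7 lists of log2(CPM + 0.5) minus the control mean of each gene, with 1 point per library (6 control in grey, 6 iNICD in red) and black bars for the mean and SD. The atrial identity medians of the iNICD libraries lie below those of the controls, and the interferon and cell cycle medians above.

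Sinus node and conduction genes changed in part. Tbx3, the repressor that sets the pacemaker program, fell from 15.3 ± 1.21 to 9.18 ± 0.976 CPM (SD, n = 6, log2 fold change -0.71, adjusted p = 0.00028). Tbx5, a transcription factor of atrial and sinus node development, fell from 308 ± 24.4 to 206 ± 20.7 CPM (-0.58, adjusted p = 0.00031), and Srf, a regulator of muscle genes, fell by 0.65 on the log2 scale. The pacemaker channel gene Hcn4 did not pass the test, with a log2 fold change of -0.23 (SE 0.35). Neither did Shox2 (-0.37), Isl1 (-0.32), Cacna1d (-0.16), Nkx2-5 (0.14), the connexins Gja1 (0.38) and Gja5 (-0.02), or the potassium channels Kcna5 (-0.47) and Kcnj3 (-0.01). By the exact permutation test, unadjusted, Gja1 had p = 0.030, and the other genes that did not pass had 0.052 (Kcna5) or more. Gja1 stayed short of the limma threshold in 11 of the 12 fits that each left out 1 library and passed it in the other.

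In the sinus node list of 18 genes, Tbx3, the T-type calcium channel gene Cacna1g (-0.80) and Cpne5 (-1.28) fell and Vsnl1 (1.36) rose (the same counts adjusted over the list alone), and camera gave adjusted p = 0.13, or 0.045 without iNICD 5. The calls of Cacna1g and Cpne5 depended on single libraries, holding in 2 and 3 of the 12 fits that each left out 1 library. The sodium channel and coupling list had camera adjusted p = 0.15. Among 25 potassium channel genes, Kcnq1 rose (0.85) and Kcnip2, a subunit of the transient outward channel, fell (-1.15), while adjusted over the list alone 4 rose and 1 fell, and camera gave adjusted p = 0.49. In the calcium handling list Sln fell and the calcium-binding gene Casq2 rose (0.31), 2 of 25 genes (adjusted over the list alone 2 rose and 2 fell), with camera adjusted p = 0.33. The Casq2 call was lost under median-of-ratios and quantile scaling and with the replicate block, and held in 2 of the 12 fits that each left out 1 library.

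A few genes of the autonomic list rose. The adenosine A1 receptor gene Adora1 went from 34.6 ± 4.09 to 127 ± 29.5 CPM (SD, n = 6, log2 fold change 1.83, adjusted p = 2.0e-06), and Adra1a (1.06), Adrb1 (0.57) and the adenylyl cyclase gene Adcy6 (0.50) rose as well. Adcy1 (-0.42) fell, so 5 of the 25 genes of the autonomic list changed (adjusted over the list alone also 5), and camera gave adjusted p = 0.84. Of 17 intercalated disc genes, Dsc2 (0.59), Dsg2 (0.67) and Ctnna3 (0.35) rose and none fell (adjusted over the list alone 5 rose), with camera adjusted p = 0.16, or 0.026 without control 4. The Dsc2, Dsg2 and Ctnna3 calls held in 6, 7 and 4 of the 12 fits that each left out 1 library, and the Ctnna3 call was lost under median-of-ratios scaling. In the cardiac transcription factor list Tbx5 and Srf fell (adjusted over the list alone 2 rose and 3 fell), with camera adjusted p = 0.48.

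**Figure D3:**
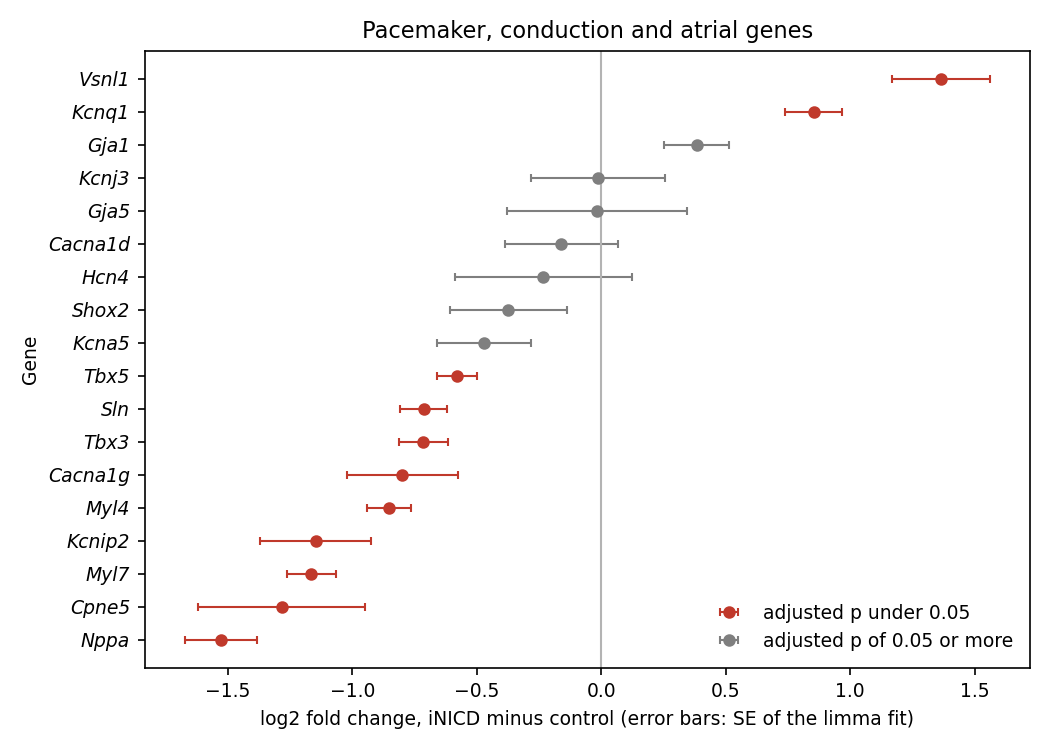
Log2 fold change of iNICD minus control for 18 pacemaker, conduction and atrial genes with the SE of the limma fit as error bars, 6 libraries per group. Red marks the 11 genes past an adjusted p of 0.05 and grey the 7 that were not, and the lowest value is that of Nppa at -1.53. The 18 genes are a selection that leaves out some reported genes that did not pass. The 11 of 18 is therefore not the share changed in the full lists. Of 18 sinus node genes 1 was higher and 3 lower, and of 18 sodium channel and coupling genes 0 and 1. Of 25 potassium channel genes 1 was higher and 1 lower, and of 15 atrial identity genes 0 and 8.

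Interferon-stimulated genes and cell cycle genes rose in iNICD. Of 21 interferon genes 16 rose and none fell (adjusted over the list alone 20 rose), including Isg15 (2.09), Irf7 (1.90), Mx1 (1.83) and the RNA sensor gene Ddx58 (0.92). The interferon list had a median log2 fold change of 0.98 and was higher by camera (adjusted p = 3.7e-17), with adjusted p = 0.35 with an estimated correlation. Of 25 cell cycle genes 18 rose and none fell (adjusted over the list alone 21 rose), including the mitotic genes Cenpf (1.66), Cdk1 (1.49) and Kif20a (0.88) and the replication gene Mcm3 (0.49). The cell cycle list had a median of 0.90 and camera adjusted p = 3.7e-12, with adjusted p = 0.35 with an estimated correlation. These genes were low, with Cdk1 at 0.616 ± 0.153 CPM in controls and 3.06 ± 2.06 CPM in iNICD (SD, n = 6). By fry, which tests each list without comparing it with other genes, the interferon (adjusted p = 0.0062), cell cycle (0.0067), Notch target (4.0e-06) and atrial identity (0.00012) lists passed the threshold.

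Macrophage markers rose to a smaller extent. Cx3cr1 (1.53), the monocyte receptor gene Ccr2 (1.21), Adgre1 (0.78) and Fcgr1 (0.75) were among 6 of 17 markers that rose (adjusted over the list alone also 6), with a list median of 0.27. The list was higher by camera (adjusted p = 0.0017), with adjusted p = 0.44 with an estimated correlation. Without the 3 libraries rich in Gm42418 and Rn7sk (control 3, iNICD 3, iNICD 5) the macrophage list had adjusted p = 0.082. The Fcgr1 call held in 7 of the 12 fits that each left out 1 library. Lymphocyte markers Trac (1.29) and Lck (1.10) rose among 7 (adjusted over the list alone also 2, camera adjusted p = 0.065), and Cxcl10 (1.54), Ccl5 (1.23) and Tnf (0.83) rose among 17 cytokine genes (adjusted over the list alone 3 rose and 1 fell, camera adjusted p = 0.81). The Tnf call was lost under median-of-ratios and quantile scaling and the Ccl5 call with a pseudocount of 0.1, and they held in 2 and 8 of the 12 fits that each left out 1 library. Mcpt4 was the one of 6 neutrophil and mast cell markers that rose, also adjusted over the list alone (camera adjusted p = 0.12). The lymphocyte list was past the threshold and higher without control 1 (camera adjusted p = 0.028), control 2 (0.039), iNICD 4 (0.043) or iNICD 6 (0.035), and also under median-of-ratios scaling (0.031), without a filter (0.00015), with edgeR (0.031), the replicate block (0.028) and the Xist covariate (0.027). The neutrophil and mast cell list was past it and higher without control 1 (camera adjusted p = 0.032) or iNICD 4 (0.042), without a filter (0.028) and with edgeR.

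The fetal and stress list, in which Nppa fell, went both ways. Mthfd2 (3.36), the asparagine synthetase gene Asns (2.48) and the pseudokinase gene Trib3 (1.65) rose, and in all 6 of 19 genes rose and 2 fell (adjusted over the list alone 7 and 2), with a list median of 0.07 and camera adjusted p = 0.49, or 0.049 with edgeR, with the list higher. Among glycolytic genes 4 of 24 fell (adjusted over the list alone also 4), namely the muscle enolase gene Eno3 (-0.80), Pgam2 (-0.52), Aldoc (-0.85) and Hk2 (-0.37). The glycolysis list was lower by camera (adjusted p = 0.0014), with adjusted p = 0.44 with an estimated correlation. The Aldoc and Hk2 calls held in 3 and 4 of the 12 fits that each left out 1 library, and the Aldoc call was lost with the replicate block. In fatty acid oxidation, Cpt1b, which imports fatty acids into mitochondria, rose (1.12) and the fatty acid carrier gene Fabp3 fell (-0.50), 2 of 30 genes (adjusted over the list alone also 2, camera adjusted p = 0.20). Of 32 oxidative phosphorylation genes Ndufa4 alone fell (-0.69, also adjusted over the list alone, camera adjusted p = 0.12). The oxidative phosphorylation list was past the threshold and lower without control 1 (camera adjusted p = 0.014) or iNICD 4 (1.5e-05), and the fatty acid oxidation list without control 1 (0.032) or iNICD 4 (0.0052), and both also with the Xist covariate (0.0070 and 0.036). In the citrate cycle list Cs (0.29) and Suclg2 (0.33) rose among 19 (adjusted over the list alone also 2, camera adjusted p = 0.84), and the Cs call was lost under median-of-ratios and quantile scaling. The Fabp3 call was lost without iNICD 1 or iNICD 2, and the Cs and Suclg2 calls were lost with the replicate block and held in 2 and 5 of the 12 fits that each left out 1 library.

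Of 34 matrix and fibrosis genes 28 had positive log2 fold changes, but few were called. Thbs4 (1.39) was the one of 34 matrix genes past the threshold, also adjusted over the list alone, and camera gave adjusted p = 0.28, or 0.0076 without control 4 and 0.037 without iNICD 6, with the list higher. It was also higher with high Xist alone (camera adjusted p = 0.00074, 4 genes called higher). Without control 4 and with the Xist covariate it was at 9.3e-06, with 5 genes called higher and 0 lower. The result for this list thus depended on single libraries, namely control 4 and iNICD 6. Col1a1 was at 226 ± 58.4 CPM in controls and 281 ± 84.8 CPM in iNICD (SD, n = 6, log2 fold change 0.30, SE 0.20), which did not pass the test. In the TGF-beta and BMP list Id1 fell (-0.50) among 26 genes (adjusted over the list alone 0, camera adjusted p = 0.082), and in the Wnt list Fzd2 (-0.56) and the secreted inhibitor gene Sfrp5 (-1.0002) fell among 23 (adjusted over the list alone 1 rose and 3 fell, camera adjusted p = 0.13). The Thbs4 call was lost without control 1, control 2, control 4, iNICD 1, iNICD 4 or iNICD 6 and with the replicate block, and the Id1 call was lost under median-of-ratios scaling and held in 2 of the 12 fits that each left out 1 library. The TGF-beta and BMP list was past the threshold and lower without control 1 (camera adjusted p = 0.034), control 2 (0.046) or iNICD 5 (0.043).

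Markers of other cell types that could be in the dissection went both ways. Among the lists lower by camera, neuron markers (adjusted p = 0.013) held 1 called gene, Dbh, which makes noradrenaline (-1.54), and adipocyte markers (adjusted p = 0.0011) held Plin4 (-0.86). Immediate early genes (adjusted p = 1.9e-05) held Nr4a1 (-1.14), and red cell markers (adjusted p = 0.0052) held none of 5. All 4 of these lists had adjusted p = 0.44 with an estimated correlation. Adjusted over the list alone, 2 neuron, 1 adipocyte, 1 immediate early and 0 red cell genes fell. Without control 4 the neuron and red cell lists were past the threshold no longer (camera adjusted p = 0.071 each), nor was the neuron list without iNICD 2 (0.052) or under quantile normalization (0.054). The Nr4a1 call held in 4 of the 12 fits that each left out 1 library. Endothelial markers were lower as a list (adjusted p = 0.028, and adjusted p = 0.47 with an estimated correlation, median -0.12), yet the one of 16 that was called, Esam, rose (0.93, also adjusted over the list alone). The endothelial call was lost without control 3 (camera adjusted p = 0.076), control 4 (0.12), iNICD 1 (0.057) or iNICD 6 (0.096), under quantile normalization (0.072) and with edgeR (0.11). Cspg4, a pericyte marker, rose (1.86) as the one of 14 smooth muscle and pericyte genes (also adjusted over the list alone, camera adjusted p = 0.60). Tcf21 rose (0.25) as the one of 14 fibroblast markers (adjusted over the list alone 1 rose and 1 fell, camera adjusted p = 0.84), a call that held in 1 of the 12 fits that each left out 1 library and was lost under median-of-ratios and quantile scaling, with edgeR, without a filter and with the replicate block.

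No member of the circadian (17 genes), epicardial (10), Schwann cell (11) or skeletal muscle (5) lists was called by limma, over all genes or adjusted over the list alone. Camera gave these lists adjusted p = 0.12, 0.065, 0.20 and 0.56. The circadian list was past the threshold and lower without iNICD 6 (camera adjusted p = 0.037), and the epicardial list without control 6 (0.024), iNICD 2 (0.0067), iNICD 3 (0.034) or iNICD 5 (0.020) and with the replicate block (0.028). The thymus, lung, thyroid and sex-linked lists held under 5 kept genes and were not tested with this filter. Without a filter, camera gave adjusted p = 0.065 for the thymus list, 0.37 for the lung list and 0.83 for the sex-linked list. Xist was above 100 CPM in controls 1, 2, 3 and 5 and in iNICD 1, 2 and 3 (464 to 649 CPM), and at 7.07 to 13.5 CPM in the other libraries, so the groups held 4 and 3 libraries with high Xist. Ddx3y, a Y-linked gene, was at 62.7 to 100 CPM in the libraries with low Xist and at 0 to 2.74 CPM in those with high Xist. Both groups therefore held libraries of male and of female pattern. Within the libraries with high Xist 916 genes were higher and 395 lower. Within the 5 with low Xist (controls 4 and 6, iNICD 4, 5 and 6) 36 were higher and 1 was lower.

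Control 4 stood apart from the other control libraries. On the first principal component, with 29.4% of the variance, it lay at -49.9 where the other controls lay at -14.4 to -9.76 and the iNICD libraries at 9.56 to 28.7. Nppb, the B-type natriuretic peptide, was at 2750 CPM in control 4 and at 153 to 445 CPM in the other controls. Thbs1 was at 274 CPM in control 4 against 12.8 to 30.2 CPM in the other controls. These genes were chosen after their values were seen. Without control 4, 782 genes were higher and 432 lower, of which 652 and 246 were among the genes called with it. The intercalated disc list (camera adjusted p = 0.026) and the matrix list (adjusted p = 0.0076, median 0.23) were past the threshold and higher without control 4.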

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

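The values in this part were picked by a fixed rule, and the tests of explanations were chosen only after the results were seen. In a group of 6 libraries, a value was taken as standing apart when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% critical value, which chance gives in about 1 of 20 groups. Of 220 groups tested (99 of the 102 named genes and 11 library measures in both groups) 18 held such a value, where chance gives 11, and 7 of the 18 were in control 4.

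In control 4, Adrb1 was at 13.3 CPM where the other controls lay at 22.6 to 25.9 CPM, Cx3cr1 at 2.17 CPM (others 4.74 to 6.21 CPM) and Kcnq1 at 48.0 CPM (others 79.1 to 83.2 CPM). Higher than in the other controls were Id1 at 140 CPM (67.5 to 79.8 CPM), Cspg4 at 105 CPM (51.7 to 71.0 CPM), Cnksr1 at 17.6 CPM (3.76 to 5.55 CPM) and Tnf at 1.08 CPM (0.157 to 0.499 CPM). Leaving out control 4 ended the call of none of these 7 genes.

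Control 2 held Aif1l at 93.1 CPM (other controls 55.2 to 64.6 CPM) and Cxcl10 at 1.91 CPM (0.255 to 0.821 CPM). Control 1 had 22750 genes above 0 (other controls 21323 to 21846), in the library of greatest depth. Control 3 had 3.57% of its reads on lincRNA genes (1.69 to 1.86% in the other controls) and 2.90% on Gm42418 and Rn7sk (0.932 to 1.37%). iNICD 1 held Plin4 at 224 CPM (other iNICD libraries 295 to 323 CPM) and Vsnl1 at 15.9 CPM (8.64 to 11.3 CPM). iNICD 4 held Casq2 at 1433 CPM (1009 to 1167 CPM) and Ndufa4 at 279 CPM (202 to 222 CPM), and iNICD 5 held Aif1l at 40.7 CPM (20.5 to 25.5 CPM) and Cntfr at 18.1 CPM (7.35 to 11.2 CPM).

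The rise of interferon genes in iNICD was set against 2 explanations. An even rise of all macrophages would raise their markers as much, but the gap between the interferon and macrophage medians was 0.81 larger in iNICD than in control (log2 scale, exact permutation p = 0.0022, n = 6 each), with 0.48 to 1.11 in iNICD libraries and -0.79 to 0.29 in controls. The interferon list was picked because it rose, which favours a gap. Single macrophage markers ranged from -0.36 to 1.53 (Cx3cr1), so the medians cannot speak to a rise of part of these cells. An imbalance of libraries with high Xist was argued against by medians of 1.16 with high Xist alone and 1.18 with low Xist alone. The low-Xist median compares iNICD 4, 5 and 6 with controls 4 and 6, of which control 4 stood apart. A response to the iNICD genotype in resident cells stays open as a hypothesis, as do other shifts in cell types, since the cells that carry these transcripts were not measured.

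The fall of atrial genes in iNICD was treated alike. An even fall in the share of cardiomyocyte RNA would lower sarcomere genes as much. The medians per library differed between the groups by -0.48 for the atrial list and by -0.14 for the sarcomere list. Their gap differed between the groups (exact permutation p = 0.0022, n = 6 each). The atrial list was picked because it fell, which favours a gap. Of single sarcomere genes, Ttn held 7.45 to 8.53% of reads in iNICD and 8.60 to 9.38% in controls, without overlap. Myh6 overlapped, at 3.55 to 4.22% in iNICD and 3.30 to 4.70% in controls. Ventricular tissue in the dissection would bring its light chain Myl2, which reached 9.98 CPM at most in iNICD, against 2284 ± 401 CPM (SD, n = 6) for Myl7. The sarcomere median lay below the control mean in 6 of 6 iNICD libraries and 3 of 6 controls, and the sarcomere list passed camera as lower in 8 of the 12 fits that each left out 1 library (adjusted p = 0.018 without control 3 to 0.049 without iNICD 3) but not with all libraries (0.052), under median-of-ratios scaling (0.13) or under quantile normalization (0.57), so a smaller myocyte share may account for part of the change. A shift of atrial identity with the iNICD genotype remains a hypothesis from the same data.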

How the results depend on the processing

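The covariate for Gm42418 and Rn7sk, the fits without the 3 libraries rich in them, with high or low Xist alone, and without control 4 with the Xist covariate were chosen after seeing the data. Notch1 stayed past the threshold in the same direction under every alternative, with log2 fold changes of 4.05 to 4.35. Of the other 88 named genes past the threshold, none turned its direction in any alternative fit, 11 kept their call in every fit, and 47 lost it in no fit but those on the libraries with high or low Xist alone. Genes higher in iNICD numbered 458 (without iNICD 1) to 782 (without control 4) with each library left out in turn, and genes lower in iNICD 186 (without iNICD 1) to 432 (without control 4). Genes lower numbered 407 with quantile normalization, 552 with array weights, 587 with DESeq2 and 451 without control 4 with the Xist covariate, and the cause was not tested. Without the 3 libraries rich in Gm42418 and Rn7sk (control 3, iNICD 3, iNICD 5) 378 were higher and 145 lower, and with low Xist alone (5 libraries) 36 were higher and 1 lower, with fewer samples in each. The only controls with low Xist were controls 4 and 6, so control 4, which stood apart, weighs on that fit. At an adjusted p of 0.01, 314 were higher and 115 lower, and with a log2 fold change of at least 1, 178 were higher and 46 lower, as stricter thresholds allow fewer genes. The edgeR test called 623 higher and 383 lower, of which 599 and 253 were among the limma calls. Gene lists higher in iNICD numbered 7 with low Xist alone, 8 without control 4 with the Xist covariate, 7 with edgeR and 0 with an estimated correlation, against 4 as reported. Gene lists lower in iNICD numbered 1 with an estimated correlation and 1 with fry, against 7, and 4 (without control 4) to 11 (without control 1 or iNICD 5) with each library left out. The atrial identity list was past the threshold and lower in each of these fits. List tests under DESeq2 were not run.

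Genes not past the threshold turned direction as follows, and the cause was not tested. Hey2 was at 0.040 with array weights, 0.14 with low Xist alone and -0.094 to 0.055 with each library left out. Gja5 was at 0.075 with the Xist covariate, 0.082 with the Gm42418 and Rn7sk covariate, 0.060 without the 3 rich libraries, 0.86 with low Xist alone and -0.34 to 0.18 with each library left out. Kcnj3 was at 0.035, 0.067, 0.13 and 0.38 in the same order of fits and -0.28 to 0.085 with each library left out. Hcn4 was at -0.40 to 0.035 with each library left out, Cacna1d at 0.010 with low Xist alone, and Col1a1 at -0.018 without the 3 rich libraries. Among the named genes not past the threshold as reported, 1 passed it with the Xist covariate, 1 with DESeq2 and 1 with high Xist alone. The same held for 1 without control 4 with the Xist covariate, 1 without iNICD 2 and 1 without iNICD 6.

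The shared numbers 1 to 6 were tried as pairs with a replicate block, although the labels do not say that a number marks a litter. Deviations of same-numbered libraries correlated at -0.0056 to 0.32, over 0.1 in 4 of 6 pairs. Of the 12 libraries 6 correlated best with their own number among the 6 of the other group, namely both libraries of numbers 1, 4 and 6. Whether this exceeds chance was not tested. Numbers 1, 2, 3, 4 and 6 also shared high or low Xist across the groups, and number 5 did not. The numbers were not used as pairs in the main test because the labels do not say what they mark. A link behind them stays open, and the main test would leave such a pairing out. With the replicate block, 794 genes were higher and 297 lower, 5 lists higher and 9 lower, and Notch1 was at 4.12. Of the reported calls 624 of 698 higher and 238 of 264 lower genes were kept, and 7 named genes lost their call (Aldoc, Casq2, Cs, Myom1, Suclg2, Tcf21 and Thbs4). With the block, 2 named genes not past the threshold as reported gained a call. With a depth of 12015650 reads in the shallowest library, genes near 1 CPM rest on few reads. Changes of 1.5-fold were recovered for 52% of the simulated genes so changed, which had means of at least 2 CPM.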

Other observations

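The other neighbours named, the chromosome 2 interval, its single-library and extra-copy tests, and the tests of GC content and co-variation were chosen only after the values or the excess of neighbouring calls were seen, and the other tests of neighbouring genes and the splits of the libraries were set before.

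Most genes on a stretch of chromosome 2 were higher in iNICD. From Ptgs1 to Ppp6c (36230426 to 39226451, GRCm38, 3.00 Mb) 21 consecutive kept genes had positive log2 fold changes and 18 of them were called higher by limma. Their mean was 0.54 (SD 0.14 over genes), a mean of 1.45-fold, with a range of 0.24 to 0.76. They include Rabgap1 (0.76), Arpc5l (0.65), the proteasome subunit gene Psmb7 (0.59) and the ribosomal protein gene Rpl35 (0.44). Relative to the control mean, the interval's mean log2 level was 0.48 to 0.63 in the 6 iNICD libraries and -0.20 to 0.12 in the 6 controls. The 42 kept genes flanking it had a median of 0.16 and 8 were called higher, against 698 of the 14336 genes tested. Past its end, Lrp1b and Arhgap15 (40595246 to 44395953) were called higher, with a mean log2 fold change of 1.72. Calls of higher genes thus went on past the chosen bounds. The interval was chosen after its values were seen, and Notch1 lies outside it on the same chromosome.

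Other neighbours were higher together. On chromosome 4, Aldh1b1 (2.61), Igfbpl1 (2.86) and Ccdc180 (2.49) lie within 188 kb with the predicted gene Gm12409 (1.83), and Agrn (0.57), Isg15 (2.09) and AW011738 (3.76) lie within 39.9 kb. On chromosome 1, Chil1, Mybph, Adora1 and Ppfia4 lie within 151 kb and had a mean log2 fold change of 1.45. The run of 21 genes with the highest median elsewhere (0.70) was on chromosome 17, from 33949909 to 34316674, which holds part of the major histocompatibility complex.

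Adjacent genes were both called higher in 118 pairs, where shuffled calls gave 33.9 on average, and both called lower in 22 pairs against 4.80 (permutation p = 0.0001 each, the smallest the shuffles can give), so the excess was not particular to higher genes. The excess of higher pairs stayed in the same permutation test without pairs of similar symbols (102 against 32.2, p = 0.0001), without overlapping genes (95 against 28.9, p = 0.0001), without chromosome 2 (93 against 31.2, p = 0.0001) and in shuffles matched on GC content as well (118 against 34.1, p = 0.0001). Without the first 3 kinds of pairs together it was 62 against 25.3 (same permutation test, p = 0.0001). Pairs of similar symbols, overlapping gene bodies and chromosome 2 thus did not account for all of it, nor did GC content alone. Reads shared between other neighbours, such as near-identical copies with unlike symbols, were not tested. Co-variation of neighbours in any grouping stays open, since 8 of the 100 splits drawn of the 12 libraries, the real one included, gave a correlation of adjacent fold changes as high as the real split (Spearman's rho 0.13 across genes, which are not independent, highest of the others 0.17). A single library was not behind the rise of the chromosome 2 interval, as the lowest iNICD library (0.48) lay above the highest control (0.12), in genes picked for being called. An extra copy of the interval was not decided, since copy number was not measured. The interval's mean lay -1.46 standard errors over genes from the log2 of 1.5 (0.58) that 3 copies against 2 give. That error treats neighbouring genes as independent. The bounds were chosen after the values were seen, so a near value cannot speak for a copy. Of the 13850 other runs of 21 genes, 3.08% had a smaller SD and 19 had a mean as high. An extra copy therefore cannot be told apart from regional regulation or other causes of a regional rise.

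Chance in the grouping of the libraries was an unlikely source of the number of changed genes. Of 100 splits drawn from the 462 possible splits of the 12 libraries into 6 and 6, 1 gave as many genes as the real split, namely the real split itself with 962 genes, and the highest of the others gave 11. A share of 1 in 100 is the smallest that this draw can give. Every other split mixed control and iNICD libraries, so a real difference adds to the spread within its sides.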
